A study of Mus musculus with 24 samples.

How the data were processed

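Total RNA was sequenced from lens epithelium and lens fiber cells that were microdissected from CD1 mice, an outbred albino stock, at embryonic days 14.5, 16.5 and 18.5 (E14.5, E16.5, E18.5) and 0.5 days after birth (P0.5). Per the design text there are 3 biological replicates of each tissue and stage, which makes 8 groups and 24 libraries. Whether a replicate pools the lenses of several animals, and whether epithelium and fiber replicates with the same number come from the same animals, is not stated in the sources used here. RNA was extracted with Trizol, ribosomal RNA was depleted, and stranded libraries were sequenced as paired-end reads on an Illumina instrument.

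The deposited table holds counts, 1 column per library, with no normalization. Per the submitters' processing notes the tools used were Trim Galore 0.4.1, TopHat2 2.0.13, HTSeq 0.6.1, Cuffdiff and Cufflinks 2.2.1 with the mouse build mm10. The notes give no role or order for these tools. The strand setting used in counting is not given in the sources used here, so reads of overlapping genes on opposite strands may be shared. Reads of near-identical genes, such as the gamma crystallins and the globins, may also be shared, and values of single members of these families are uncertain for that reason. The values were checked to be whole numbers whose totals differ between libraries. The table lists 12611 gene symbols, and how they were selected is not stated. Of these symbols, 12340 (97.9%) match exactly 1 gene of GENCODE M21 (GRCm38, the same assembly as mm10), from which the coordinates are taken.

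The total count was 7658794 to 11819117 in epithelium libraries and 13010174 to 21617737 in fiber libraries. Replicates were not copies of each other: the chi-square per degree of freedom between replicates ranged from 3.27 to 13.3. Counting intervals and limits given below cover counting error only, since the reads carry no molecular identifiers.

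Genes were kept with the filterByExpr function of edgeR 4.0.16 (minimum count 10, minimum total count 15), which left 12427 genes to test and removed 184, of which 46 had no count in any library. Libraries were scaled with TMM, which assumes that most genes do not differ. All 24 libraries entered 1 quasi-likelihood fit of the 8 group means (16 residual degrees of freedom, biological coefficient of variation 0.0847). Each comparison was a contrast of that fit. P-values are two-sided and were adjusted with the Benjamini-Hochberg method over all genes tested. A gene passed the test at an adjusted p under 0.05 and a change of at least 2-fold, and the words rose, fell and changed are used only of such genes. An exact permutation test of 3 against 3 libraries cannot give a p under 0.1, so no rank test is given. CPM values are those of edgeR's cpm function, counts relative to the TMM-adjusted library size, and errors of CPM are SD over 3 libraries. Errors of log2 changes of single genes, marked SE, are the absolute log2 change divided by the square root of the F value of the quasi-likelihood test. They can be too small where a group is near 0 counts.

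The comparisons were fiber against epithelium at each stage and averaged over 4 stages, each stage against the one before it and P0.5 against E14.5 within each tissue, and the change of the fiber to epithelium difference from E14.5 to P0.5 (an interaction). Named genes are the 10 with the largest rise and the 10 with the largest fall in the 3 main comparisons (the averaged one and P0.5 against E14.5 in each tissue), and the 3 largest each way in the others. They had to pass the test, reach a mean of 50 CPM in the higher group and not be predicted genes, histones, small noncoding RNAs or immunoglobulin or T cell receptor segments. Members of the gene lists are also named.

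The gene lists, 27 in all, were written before the data were examined, as were the comparisons, the tests of genes and lists, the naming rule and the alternatives, except for 5 settings named below. Of the tests of explanations, some were chosen only after the result was seen, and the closing part says which. They cover crystallins, fiber structure, epithelium markers, lens transcription factors, proliferation, cell cycle exit, autophagy and organelle loss, the FGF, Notch, BMP and TGF-beta, and Wnt pathways, chromatin remodelers, basement membrane, glycolysis and hypoxia, antioxidant genes, cholesterol synthesis, ribosomal proteins, oxidative phosphorylation and long noncoding RNAs. The other 8 hold markers of endothelium, mural cells, macrophages, red cells, mesenchyme, retina, pigment cells and cornea. Some genes stand in more than 1 list, such as Dnase2b and Fyco1 in fiber structure and autophagy, Foxe3 and Pax6 in epithelium markers and transcription factors, and Sfrp2 in epithelium markers and Wnt. Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests whether the genes of a list move, on balance, one way and does not compare them with other genes. These p-values were adjusted over the 27 lists.

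On simulated data for epithelium P0.5 against E18.5 (12416 genes tested, 50 changed genes per fold) edgeR recovered 0% of the genes changed 1.5-fold, 48% of those changed 2-fold and 100% of those changed 3- or 4-fold, with 6 false calls. DESeq2 recovered 48% at 2-fold with 3 false calls. A call needs a fitted change of at least 2-fold, so the shares at 1.5-fold and 2-fold largely follow from that threshold. With no list changed, camera called 0 of the 27 lists, camera with an estimated correlation 0 and fry 1. Each gene was drawn independently there, so the simulation does not test the list tests under correlation between the members of a list. In a separate simulation of fiber against epithelium at E14.5, the stage with the lowest crystallin share in fiber, the crystallins alone were set to their fiber level (12415 genes tested). There TMM called 1 gene that was not raised, and scaling to library size called 106 such genes. Only the crystallins differ in that simulation, so the assumption of TMM holds in it by design. In the data 9537 of 12427 genes had an adjusted p under 0.05 at E14.5 without a fold threshold. The simulation does not test TMM under such a broad difference.

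The alternatives tried were no filter, a filter of 5 CPM, median of ratios scaling, library size only, crystallins left out with the rest scaled to the same total, the Wald test of DESeq2 1.42.0, only the groups compared in the fit, the replicate number as a block, no fold threshold or a 4-fold one, and each library left out in turn. Added after the data were seen were a fit without Rn45s, Lars2 and Mir6236, a fit without the genes of the lists for other cell types, a block for each stage and replicate number, the average over E14.5 and E16.5 alone, and E16.5 in place of P0.5. R 4.3.3 and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. List genes that are absent from the table, such as Ptprc, Nrl, Ttr, Krt5, Krt14 and Trp63, were not analysed here, the adult globins Hba-a1 and Hbb-bs had no count in any of the 24 libraries, for a reason that is not stated, and the glycolytic gene Eno1 did not pass the filter. No library was left out of the main comparisons.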

Results

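Gene expression was measured by total RNA sequencing in 12 libraries of lens epithelium, the layer of dividing cells that covers the front of the lens, and 12 libraries of lens fiber cells, which arise from the epithelium, elongate, lose their organelles and make up the bulk of the lens. Each tissue was sampled at E14.5, E16.5, E18.5 and P0.5 with 3 biological replicates per stage. The total count per library was 7658794 to 11819117 in epithelium and 13010174 to 21617737 in fiber. The 16 crystallin genes, which encode the structural proteins that give the lens its refractive power, took 1.91% ± 0.24 (SD, n = 3) of the counts in E14.5 epithelium and 3.70% ± 0.76 in P0.5 epithelium. In fiber they took 24.5% ± 1.19 at E14.5, 27.1% ± 2.59 at E16.5, 33.9% ± 3.93 at E18.5 and 43.2% ± 0.61 at P0.5. The ribosomal RNA precursor Rn45s took 3.98% to 28.9% of a library's counts, the most in E18.5 fiber replicate 2. On principal components of log2 CPM, PC1 (79.7% of the variance) separated the tissues and PC2 (10.2%) separated E14.5 and E16.5 libraries from E18.5 and P0.5 libraries in each tissue.

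**Figure D1:**
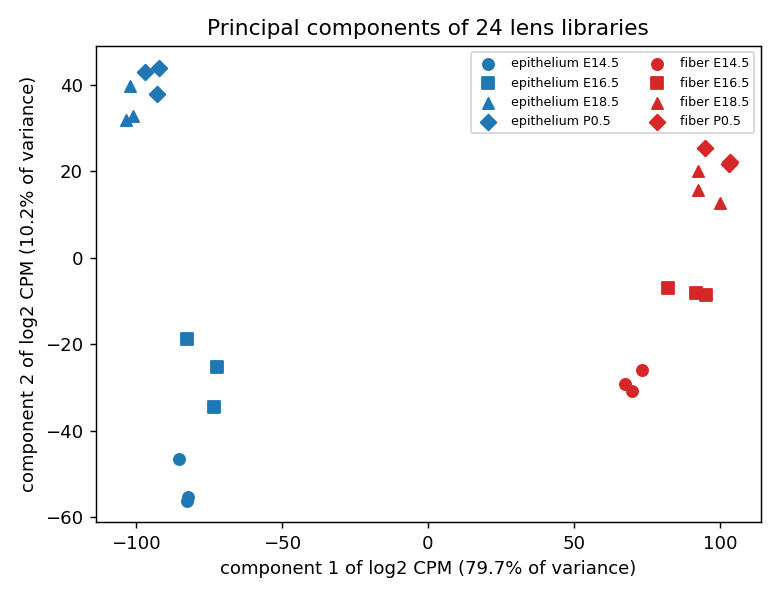
Scores of the 24 libraries on PC1 (79.7% of the variance) and PC2 (10.2%) of log2 CPM, 1 point per library, with tissue and stage marked. Fiber and epithelium lie on opposite sides of PC1, and the 3 replicates of each group lie near each other.

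Fiber against epithelium asks which genes distinguish the differentiated cells from the cells they arise from. Crystallin genes were far higher in fiber: Crygd stood at 8946 CPM ± 597 (SD, n = 3) in fiber and 110.5 ± 8.34 in epithelium at E14.5, and at 33970 ± 1430 against 194.0 ± 65.5 at P0.5. Genes of the cell division machinery were far lower: Bub1, a spindle checkpoint kinase, stood at 4.47 CPM ± 0.21 in fiber and 72.8 ± 3.15 in epithelium at E14.5. Rankings of genes here and below cover only genes that pass the test, reach a mean of 50 CPM in the higher group and are of the types given in the methods. Averaged over 4 stages, the largest rise was that of Scnn1b, a subunit of the epithelial sodium channel (143-fold, log2 7.16 ± 0.10 SE, edgeR adjusted p = 3.44e-26). It was followed by Crygb, Cryga, Crygd and Crygf (107- to 117-fold), the potassium channel gene Kcnj6 (101-fold), Cryge (99.0-fold), Dnase2b (97.4-fold), Pla2g7 (93.0-fold) and Cryba4 (88.5-fold). Dnase2b encodes the DNase that degrades the nuclear DNA of fiber cells, and its CPM in fiber went from 53.0 ± 3.11 at E14.5 to 269 ± 62.3 at P0.5. The largest falls were those of Lrtm1 (log2 -6.16), R3hdml (-6.02), Igfbp5 (-5.94) and Lama4, a laminin chain of vessel walls (-5.67). They were followed by Arsi (-5.52), the vessel markers Cd34 (-5.43), Eng (-5.20) and Cdh5 (-5.19), Bub1 (-5.32) and Col15a1 (-5.21). On GRCm38, Scnn1b lies at chromosome 7, 121865038 to 121918514; Crygd at chromosome 1, 65061872 to 65063452; Dnase2b at chromosome 3, 146580985 to 146615596; Bub1 at chromosome 2, 127801122 to 127831865; and Lama4 at chromosome 10, 38965515 to 39110188, all protein-coding.

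All 16 crystallin genes were at least 2-fold higher in fiber on average, with a median log2 difference of 5.69 (camera adjusted p = 1.54e-14; adjusted p = 0.0652 with an estimated correlation). Of 20 fiber structure genes 18 were higher, among them Bfsp1, of the beaded filament of fiber cells (6.24), the membrane channel gene Mip (5.51) and Lim2 (4.87), while Cdh2 (0.27) and Fyco1 (0.70) did not pass (camera adjusted p = 5.63e-15). Of 12 epithelium markers 10 were lower, such as the connexin gene Gja1 (-4.96), Cdh1, which encodes E-cadherin (-4.67), and the transcription factor gene Foxe3 (-3.80; camera adjusted p = 4.44e-06). All 26 proliferation genes were lower, with a median of -4.17, for example Top2a (-4.74) and Mki67 (-4.61; camera adjusted p = 7.79e-21). Of 12 cell cycle exit genes 5 were lower, 8 with library size only, among them Cdkn2c (-2.96) and Cdkn1a (-2.22), while Cdkn1b (0.28) and Cdkn1c (0.66) did not pass 2-fold (camera adjusted p = 0.134). The 19 lens transcription factor genes went both ways, 6 higher, such as Hsf4 (5.46), Maf (2.55) and Sox1 (1.99), and 8 lower, such as Six6 (-3.64), Pax6 (-1.69) and Sox2 (-1.45; camera adjusted p = 0.44). Their median was 0.13 with TMM, -1.08 with library size only (2 higher, 11 lower) and -0.55 with crystallins left out (4 higher, 9 lower), and their mean was -0.21. In the autophagy and organelle loss list 10 of 20 genes were higher, among them Gabarapl1 (2.99), Tfeb (1.94), Bnip3 (1.51) and Ctsd (1.40), with a median of 0.99 that turns to -0.22 with library size only (camera adjusted p = 1.25e-05). With library size only, 2 of these genes were higher and 5 lower, and with crystallins left out 3 were higher and 2 lower. Adjusted over the list alone, the counts were the same for each of the 27 lists in this comparison. The camera calls of fiber structure, epithelium markers, proliferation and autophagy hold with an estimated correlation (adjusted p = 0.00325, 0.034, 0.0402 and 0.00325).

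**Figure D2:**
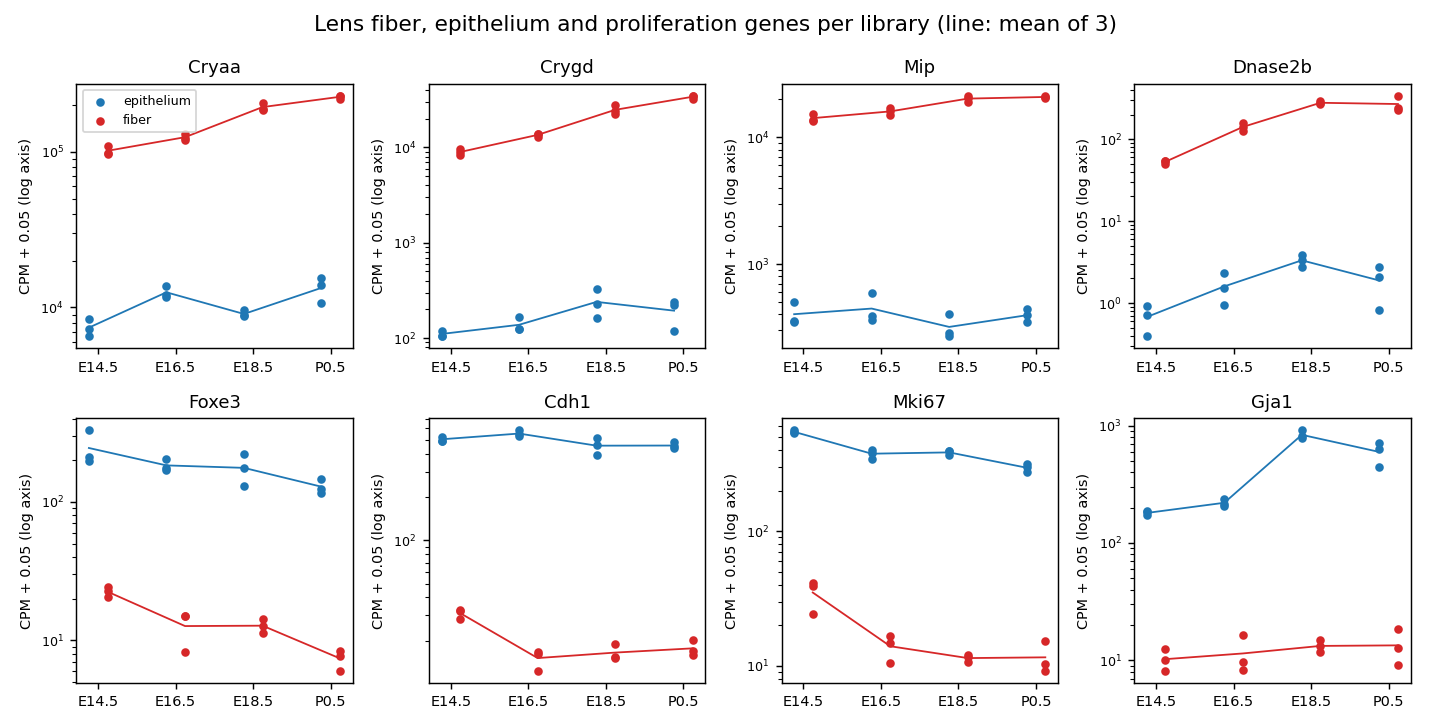
CPM (log axis, 0.05 added) of 8 lens genes by stage, 1 point per library and lines through the mean of 3 libraries. Cryaa, Crygd, Mip and Dnase2b lie higher in fiber, and Foxe3, Cdh1, Mki67 and Gja1 higher in epithelium, at each stage.

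Genes of signaling pathways were split between the tissues. Of 14 Notch pathway genes 9 were lower in fiber, such as Heyl (-4.24) and Notch2 (-3.14), and the ligand gene Jag1 was higher (1.21; camera adjusted p = 0.00355; adjusted p = 0.195 with an estimated correlation). Of 20 Wnt pathway genes 11 were lower, such as Lef1 (-4.89) and Fzd2 (-4.32), and 5 higher, such as Wnt7a (3.77), or 2 higher with library size only or with crystallins left out (camera adjusted p = 0.372). Of 17 BMP and TGF-beta pathway genes 9 were lower and 3 higher, Id2 (4.0), Bmpr1b (3.15) and Id1 (2.16; camera adjusted p = 0.23). Of 16 FGF pathway genes 5 were higher, such as Spry1 (3.24) and Fgfr3 (1.99), and 4 lower, such as Dusp6 (-1.82; camera adjusted p = 0.552), with a median of -0.20 and a mean of 0.15, and 1 was higher and 9 lower with library size only. Of 18 basement membrane genes 10 were lower, such as Col18a1 (-3.79) and Agrn (-3.54), and Lama3 was higher (1.38; camera adjusted p = 0.00942; adjusted p = 0.302 with an estimated correlation). Among 18 chromatin remodelers Chd3 (-2.32) and Smarcd3 (-1.17) were lower with TMM, 14 with library size only and 9 with crystallins left out (camera adjusted p = 0.189).

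Of 20 oxidative phosphorylation genes 14 were higher in fiber with TMM, such as Ndufb8 (1.63) and Sdhb (1.58), with a median of 1.27, and none passed with library size only (median 0.06) or with crystallins left out (median 0.59; camera adjusted p = 1.31e-05; adjusted p = 0.195 with an estimated correlation). Of 16 cholesterol synthesis genes 9 were higher with TMM, such as Lss (2.08) and Fdft1 (1.83), with a median of 1.09 that turns to -0.11 with library size only, where 0 were higher and 1 lower, and 2 were higher with crystallins left out (camera adjusted p = 0.00622; adjusted p = 0.54 with an estimated correlation). Of 18 glycolysis and hypoxia genes 4 were higher, such as Aldoc (1.71) and Pgk1 (1.14), and 5 lower, such as the glucose transporter genes Slc2a3 (-3.51) and Slc2a1 (-1.90; camera adjusted p = 0.938); with library size only 0 were higher and 11 lower. Of 20 antioxidant genes 4 were higher, Hmox1 (4.90), Gss (3.60), Gstp1 (3.34) and Gpx1 (2.81), and 4 lower, and their median of 0.47 turns to -0.73 with library size only and -0.20 with crystallins left out, each with 4 higher and 8 lower (camera adjusted p = 0.201). Of 25 ribosomal protein genes 1 was higher, with a median of 0.56 that turns to -0.64 (5 lower) and -0.11 (1 lower) under the same settings (camera adjusted p = 0.134). Of 11 long noncoding RNAs 7 were higher, such as Malat1 (2.63), Neat1 (2.18) and Miat (1.91; camera adjusted p = 0.139), and with library size only 1 was higher and 3 lower, with crystallins left out 4 and 1.

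Most markers of other cell types were lower in fiber. All 10 endothelium markers were lower, such as Cdh5 at 71.7 CPM ± 4.99 in E14.5 epithelium and 1.99 ± 1.19 in E14.5 fiber (list median -4.90; camera adjusted p = 0.000413; adjusted p = 0.302 with an estimated correlation). All 7 mural cell markers tested were lower, such as Rgs5 (-5.16; camera adjusted p = 0.00385; adjusted p = 0.189 with an estimated correlation), and so were all 8 macrophage markers tested, such as C1qa (-3.60; camera adjusted p = 0.134). Of 6 red cell genes 4 were lower (camera adjusted p = 0.552), and of 10 mesenchyme markers 8, such as Col3a1 (-3.02; camera adjusted p = 0.0743). Of 10 retina markers 9 were lower, such as Rax (-3.24), and Rcvrn was higher (2.28; camera adjusted p = 0.44). Of 8 pigment cell markers 7 were lower, such as Tyrp1 (-3.89), and Mitf was higher (2.80; camera adjusted p = 0.248). Of the cornea markers Pkp1 was lower (-2.90) and Perp did not pass 2-fold (0.99; camera adjusted p = 0.881).

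More genes differed at E18.5 and P0.5 than at E14.5 and E16.5. At E14.5, 1736 genes were higher and 2407 lower in fiber, at E16.5 1816 and 2534, at E18.5 2162 and 3005, and at P0.5 2177 and 3043. Averaged over the stages 1945 were higher and 2758 lower. At all 4 stages 1294 genes were higher and 2030 lower, and 47 genes were higher at 1 stage and lower at another. The 3 largest rises were Crygb (6.59), Crygf (6.54) and Nlrc5 (6.42) at E14.5, Cryga (6.80), Crygb (6.69) and Crygd (6.61) at E16.5, Scnn1b (7.82), Cryba4 (6.84) and Cryge (6.84) at E18.5, and Scnn1b (8.46), Kcnj6 (7.52) and Cryga (7.51) at P0.5. The 3 largest falls were R3hdml (-5.86), Lama4 (-5.75) and Igfbp5 (-5.62) at E14.5, Lrtm1 (-7.05), R3hdml (-6.47) and Arsi (-6.21) at E16.5, Tbx20 (-6.73), Optc (-6.48) and Slc16a10 (-6.46) at E18.5, and Slc16a10 (-6.42), Zic4 (-6.41) and Nkd2 (-6.23) at P0.5. In epithelium Tbx20 went from 2.64 CPM at E16.5 to 73.55 at E18.5, Zic4 from 3.1 to 53.3 and Nkd2 from 5.13 to 60.2. Optc and Slc16a10 rose in the same step, as did pigment and retina markers. Whether the falls of these genes reflect lens epithelial cells or other cells of the epithelium libraries was not tested. Between E14.5 and P0.5, which share no library, 1375 genes were higher in fiber at both stages (304 by chance if the calls were independent) and 2134 lower at both (589 by chance). How many genes are higher and lower depends on the scaling: the median log2 difference of all genes tested, averaged over stages, was -0.03 with TMM, -1.23 with library size only and -0.71 with crystallins left out. Higher and lower counts with library size only were 751 and 5147 at E14.5, 632 and 6733 at E16.5, 537 and 8557 at E18.5, 526 and 8439 at P0.5, and 587 and 7423 averaged. With crystallins left out they were 1041 and 3520, 853 and 4609, 804 and 5977, 997 and 5132, and 865 and 4841.

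**Figure D3:**
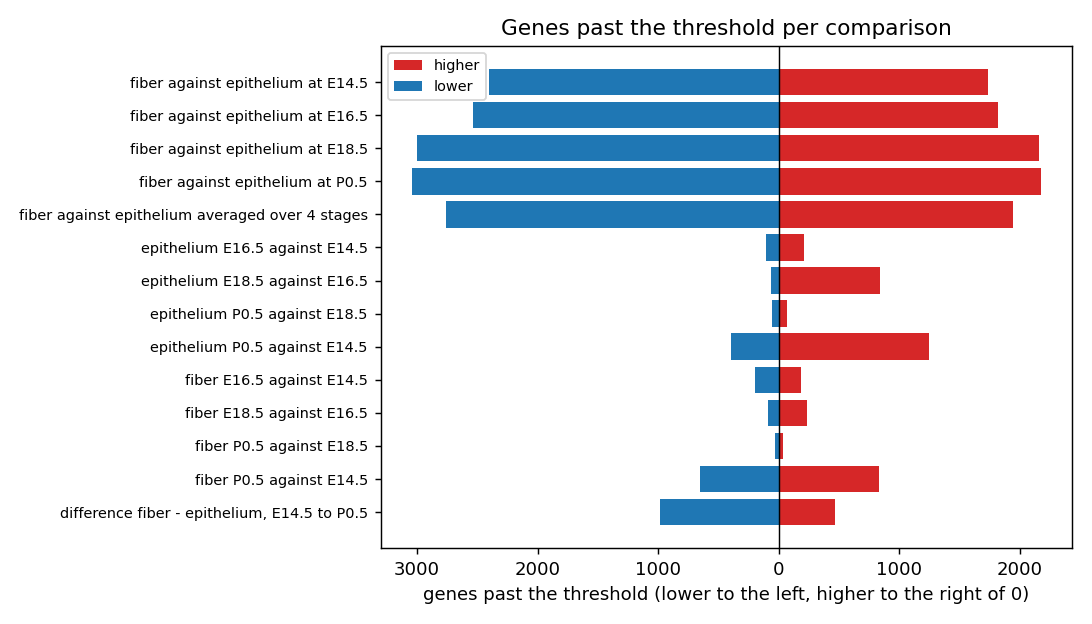
Numbers of genes at least 2-fold higher or lower (edgeR adjusted p under 0.05) in each comparison, as bars from 0. Fiber against epithelium gives the most genes and P0.5 against E18.5 in fiber, with 67, the fewest.

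Within epithelium, P0.5 against E14.5 asks how the layer changes up to birth. Among genes that reach 50 CPM, the largest rises were those of Col4a4 (log2 8.66 ± 0.46 SE, edgeR adjusted p = 5.19e-13), Slc13a4 (7.55) and Col4a3 (7.13 ± 0.31). Col4a3 and Col4a4 encode chains of the type IV collagen of mature basement membranes. Col4a3 went from 2.16 CPM ± 0.77 (SD, n = 3) to 300 ± 39.5, and Col4a4 from 0.984 ± 1.03 to 392 ± 51.6. Optc (7.06), Crhbp (6.50), Col9a3 (6.26), Htra1 (6.08, edgeR adjusted p = 2.72e-16), Lrrn1 (5.99), Zic4 (5.88) and Fam129a (5.76) followed. At E14.5 the SD also exceeded the mean for Slc13a4 (0.273 CPM ± 0.422), Crhbp (0.87 ± 1.23) and Zic4 (0.97 ± 1.02). The sizes of the rises of these genes and of Col4a4 are uncertain for that reason. Crhbp went from 3.51 CPM at E16.5 to 70.0 at E18.5, Lrrn1 from 9.23 to 175 and Zic4 from 3.1 to 53.3. Pigment and retina markers rose in the same step, while Col4a4 already stood at 40.2 CPM at E16.5. Whether the rises named here lie in lens epithelial cells or in other cells of these libraries was not tested. The embryonic globin gene Hbb-y fell most, from 8500 counts over the 3 E14.5 libraries to 2 at P0.5, a scaled ratio of 4780 (95% counting interval 1320 to 39500). Sfrp2, a Wnt antagonist, fell by 5.55 on the log2 scale (edgeR adjusted p = 1.02e-13), from 397 CPM ± 117 to 8.55 ± 3.14, and Lin28b, an inhibitor of let-7 processing, by 2.36 (edgeR adjusted p = 1.43e-14). Other falls were those of Lrtm1 (-3.51), Col3a1 (-3.50), Peg10 (-2.91), Trpc6 (-2.57), the imprinted RNA H19 (-2.55) and Greb1 (-2.48). Lars2 (-4.01, edgeR adjusted p = 0.0307) rests on 1 library: without E14.5 epithelium replicate 1 its log2 change was 0.31. It did not pass without P0.5 epithelium replicate 1 (-4.18), 2 (-3.85) or 3 (-4.02) either. Col4a4 lies at chromosome 1, 82448423 to 82586849, Col4a3 beside it at 82586921 to 82722059, Sfrp2 at chromosome 3, 83766321 to 83774316, and Lin28b at chromosome 10, 45376620 to 45486395.

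In epithelium 17 of 26 proliferation genes fell, such as Bub1 (-1.37), Ccnb1 (-1.31) and Top2a (-1.25), 9 with crystallins left out and 11 with library size only (median -1.04; camera adjusted p = 1.97e-17). Mki67 stood at 547 CPM ± 11.9 at E14.5 and 296 ± 21.6 at P0.5. Of 16 crystallin genes 5 rose, among them Crybb2 (4.24), Cryab (1.97) and Crygs (1.69; camera adjusted p = 0.000745; adjusted p = 0.534 with an estimated correlation). Of 20 autophagy and organelle loss genes 4 rose, Dnase2b (1.57), Ctsd (1.37), Tfeb (1.27) and Pink1 (1.10; camera adjusted p = 0.000421). Dnase2b was low in epithelium, at 0.625 CPM ± 0.265 at E14.5 and 1.835 ± 0.975 at P0.5, and the libraries overlapped. It stood at 269 CPM in P0.5 fiber, and whether fiber RNA in the epithelium libraries adds to this rise was not tested. Of 20 fiber structure genes 7 rose (camera adjusted p = 0.0676), and Aqp5 was at least 8.14-fold higher at P0.5 than a limit of 3 counts over the E14.5 libraries, which had none. Of 12 epithelium markers Aqp1 (4.49) and Gja1 (1.73) rose and Sfrp2 fell (camera adjusted p = 0.0676). Gja1 stood at 205.3 to 237.5 CPM at E16.5 and 784 to 908 at E18.5, the step in which pigment and retina markers rose. Whether its rise, or that of other genes here, lies in lens epithelial cells or in other cells of these libraries was not tested. Of 18 basement membrane genes 5 rose, Hspg2 (1.08) among them, and Lama3 (-1.68) and Lama4 (-1.13) fell (camera adjusted p = 0.000278; adjusted p = 0.162 with an estimated correlation). Bmp4 (5.56), Bmp2 (3.26) and Id1 (1.66) rose among the BMP and TGF-beta genes (camera adjusted p = 0.0169; adjusted p = 0.225 with an estimated correlation). Among transcription factor genes Six6 rose (3.97) and Sall4 fell (-6.90; camera adjusted p = 0.554), and the cholesterol synthesis list had a median of -0.68 (camera adjusted p = 0.00251; adjusted p = 0.534 with an estimated correlation). Markers of other cell types moved with these genes: 9 of 10 retina markers rose (median 3.43; camera adjusted p = 0.005; adjusted p = 0.389 with an estimated correlation) and 7 of 8 pigment cell markers, such as Tyrp1 (5.95) and Rlbp1 (4.6; camera adjusted p = 1.34e-06; adjusted p = 0.145 with an estimated correlation). All 6 red cell genes tested fell (camera adjusted p = 5.79e-09), and 6 of 10 mesenchyme markers, such as Col3a1 and Col1a2 (-1.87; camera adjusted p = 0.0169, or adjusted p = 0.0523 without P0.5 epithelium replicate 3 and 0.357 with an estimated correlation; 1.96e-06 to 0.357 over all alternatives). Rgs5 (2.58) and Acta2 (2.24) of mural cells and Lyve1 (2.08) and Mrc1 (1.04) of macrophages rose. Adjusted over the list alone, each count was the same. The camera calls of proliferation, autophagy and the red cell genes hold with an estimated correlation (adjusted p = 0.0483, 0.0483 and 0.00685).

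From E14.5 to P0.5, 1249 genes rose and 399 fell in epithelium, and the step from E16.5 to E18.5 had the most rises. From E14.5 to E16.5, 212 rose, led by Fam210b (2.73), Slc15a2 (2.23) and Cwc22 (2.05), and 102 fell, led by Hbb-y (-6.12), Sfrp2 (-2.85) and Col3a1 (-1.83). From E16.5 to E18.5, 839 rose and 68 fell. Optc, a proteoglycan gene that the ciliary body expresses, rose most among genes that reach 50 CPM (5.51, edgeR adjusted p = 4.30e-11), from 2.60 CPM ± 2.90 to 115 ± 20, followed by Slc13a4 (5.01) and Slc16a10 (4.90), and Lrtm1 (-2.11), Sfrp2 (-1.73) and Lin28b (-1.42) fell most. In E16.5 epithelium Slc13a4 ranged from 0.0775 to 4.12 CPM and Slc16a10 from 0.388 to 5.17. The sizes of the rises of Optc, Slc13a4 and Slc16a10 in this step are uncertain for that reason. In the same step 7 of 8 pigment cell markers rose, such as Tyr (5.91) and Dct (5.24; camera adjusted p = 2.17e-17; adjusted p = 0.0108 with an estimated correlation), and 9 of 10 retina markers, such as Rax (3.22; camera adjusted p = 0.00116; adjusted p = 0.248 with an estimated correlation). Tyrp1 stood at 0.710 CPM at E14.5, 1.30 ± 0.52 at E16.5, 49.3 ± 5.91 at E18.5 and 41.8 ± 13.7 at P0.5. From E18.5 to P0.5, with 125 genes in all (80 with a filter of 5 CPM), 72 rose, led by Crybb2 (2.01), Ppl (1.66) and the cold-inducible Cirbp (1.48), and 53 fell, led by the lactate transporter gene Slc16a3 (-1.67), Fgf15 (-1.11) and Igfbp5 (-1.03). Cwc22 did not pass without E14.5 epithelium replicate 1 (2.19) or 3 (1.67) or E16.5 epithelium replicate 1 (1.17). Fgf15 did not pass without E18.5 epithelium replicate 3 (-0.75) or P0.5 epithelium replicate 1 (-1.03) or 3 (-0.87), with DESeq2 (adjusted p = 0.116) or with only the groups compared (adjusted p = 0.0627), nor Igfbp5 without E18.5 epithelium replicate 1 (-0.97) or 2 (-0.94) or P0.5 epithelium replicate 3 (-0.79).

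**Figure D4:**
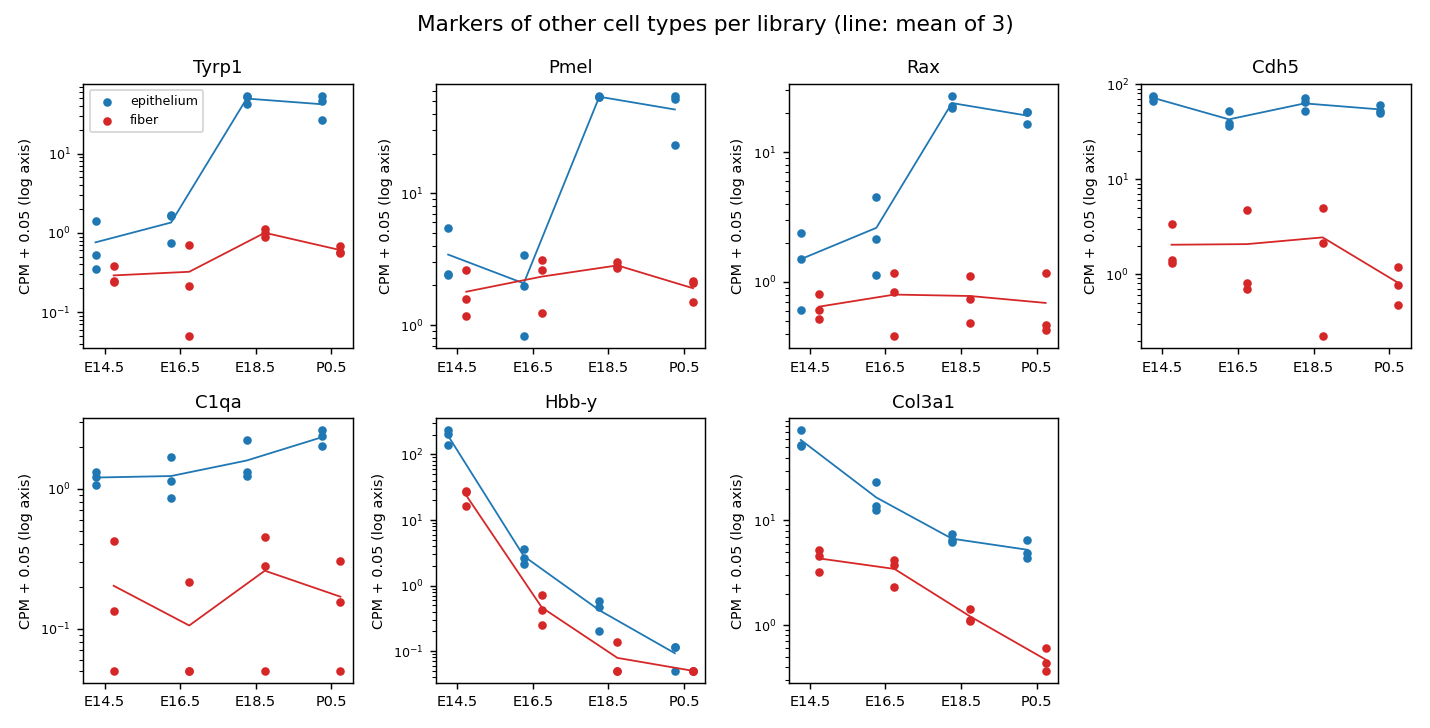
CPM (log axis, 0.05 added) of 7 markers of other cell types by stage, 1 point per library and lines through the mean of 3 libraries. In epithelium, Tyrp1, Pmel and Rax lie higher at E18.5 and P0.5 than before, and Hbb-y and Col3a1 lie lower.

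Within fiber, P0.5 against E14.5 asks how fiber cells change as they mature. Among genes that reach 50 CPM, Crybb2 rose most (log2 9.16 ± 0.48 SE, edgeR adjusted p = 2.83e-13), from 3.48 CPM ± 0.20 (SD, n = 3) at E14.5 to 19.3 at E16.5, 1004 ± 420 at E18.5 and 1978 ± 731 at P0.5. It was followed by Clic5 (8.23), Col4a4 (6.89), Cd44 (5.82) and Fabp5, a fatty acid binding protein gene (5.71, edgeR adjusted p = 2.29e-15). Crygs (4.92), Cryab, which encodes the small heat shock protein alpha-B crystallin (4.31), Tbc1d30 (4.14), Ppl (4.10) and Zfyve28 (3.65) came next. The largest falls among genes that reach 50 CPM were those of the long noncoding RNA Miat (-3.89, edgeR adjusted p = 2.17e-11), from 653 CPM ± 50.6 to 44.1 ± 3.02, and the growth factor gene Igf2 (-2.80, edgeR adjusted p = 2.13e-11), from 2478 ± 64.8 to 356 ± 18.8. Fam43a (-2.60), Fam198b (-2.37), H19 (-2.25), Mest (-2.06), Grb10 (-2.04), Sned1 (-1.91) and the protease gene Capn3 (-1.88) followed. Igf2, H19, Mest and Grb10 are imprinted genes. Cwc22 (-2.08, edgeR adjusted p = 0.0171) did not pass without E14.5 fiber replicate 1 (-1.69) or P0.5 fiber replicate 1 (-1.81) or 2 (-1.72). Crybb2 lies at chromosome 5, 113058258 to 113070117, Clic5 at chromosome 17, 44188584 to 44280172, Fabp5 at chromosome 3, 10012548 to 10016607, Miat at chromosome 5, 112213228 to 112229395, and Igf2 at chromosome 7, 142650766 to 142666816.

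In fiber 15 of 16 crystallin genes rose, all but Crygn (0.96), and 8 rose with library size only (median 1.59; camera adjusted p = 3.84e-14; adjusted p = 0.101 with an estimated correlation). Cryaa rose 2.22-fold, to 225100 CPM ± 5300. Of 20 fiber structure genes 10 rose, such as Lgsn (7.26), Hspb1 (4.96), Aqp5 (3.37) and Bfsp1 (2.09; camera adjusted p = 8.20e-11). Of 26 proliferation genes 18 fell, such as Bub1 (-2.88) and Mki67 (-1.58; median -1.59; camera adjusted p = 8.45e-09; adjusted p = 0.215 with an estimated correlation). Of 20 autophagy and organelle loss genes 5 rose, Dnase2b (2.34), Gabarapl1 (1.52), Bnip3 (1.41), Pink1 (1.04) and Sqstm1 (1.02), with a list median of 0.32 that turns to -0.23 with library size only, where 1 gene rose (camera adjusted p = 1.56e-06). Of 18 glycolysis and hypoxia genes Aldoc (3.50), Egln3 (1.77), Pdk1 (1.47) and Aldoa (1.32) rose, and with library size only 2 rose and 2 fell (camera adjusted p = 0.000495; adjusted p = 0.215 with an estimated correlation). The antioxidant genes Hmox1, from 56.2 CPM ± 8.01 to 433 ± 87.8 (2.95), Gpx4 (1.21) and Gstp1 (1.07) rose, while the median of the list, 0.39, turns to -0.16 with library size only, where 1 gene rose and 1 fell (camera adjusted p = 0.01; adjusted p = 0.229 with an estimated correlation). The long noncoding RNAs Rian (2.71), Meg3 (2.65) and Mirg (2.31) rose and Miat, H19 and Kcnq1ot1 (-1.05) fell (camera adjusted p = 0.424). Sfrp2 (-5.29), Foxe3 (-1.60) and Pdgfra (-1.34) fell among epithelium markers (camera adjusted p = 0.671), and all 6 red cell genes tested fell (camera adjusted p = 0.000539; adjusted p = 0.101 with an estimated correlation), Hbb-y to at least 236-fold below its E14.5 level at a limit of 3 counts over the P0.5 libraries, which had none. At the same limit Hbb-bh1, at 0.176 CPM in E14.5 fiber, fell by at least 1.75-fold only, so its fall past 2-fold rests on the fitted value. Of 10 mesenchyme markers 6 fell, such as Col3a1 (-3.25), and Foxc1 rose (2.01; camera adjusted p = 0.0634). Adjusted over the list alone, each of these counts was the same except that of mesenchyme, where 7 fell. The camera calls of fiber structure and autophagy hold with an estimated correlation (adjusted p = 0.0447 and 0.0215).

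From E14.5 to P0.5, 831 genes rose and 651 fell in fiber. The counts were 367 and 2168 with library size only, where the median of all genes was -0.56, and 656 and 848 with crystallins left out, where it was -0.16. From E14.5 to E16.5, 181 rose, led by Fabp5 (2.60), Rian (2.33) and Meg3 (2.21), and 200 fell, led by Mest (-1.43), Sned1 (-1.30) and Ppp1r16b (-1.12), which did not pass without E14.5 fiber replicate 3 (-0.89). With library size only these counts were 119 and 359, and with crystallins left out 117 and 296. The sizes of 2 rises of this step are uncertain, since in E16.5 fiber Rian ranged from 27.7 to 154.5 CPM and Meg3 from 66.1 to 291.7. In that step 17 of 26 proliferation genes fell (camera adjusted p = 3.06e-26; adjusted p = 0.0315 with an estimated correlation). From E16.5 to E18.5, 237 rose, led by Crybb2 (5.70), Tbc1d30 (3.92) and Fabp5 (2.75), and 90 fell, led by Miat (-2.31), Igf2 (-1.53) and H19 (-1.24), against 127 and 353 with library size only and 151 and 188 with crystallins left out. From E18.5 to P0.5, 37 rose and 30 fell, against 34 and 22 with library size only and 123 and 21 with crystallins left out; the total of 67 was 31 with only the groups compared. They were led by Rps2 (2.42), Col4a4 (1.5), Cd44 (1.44) and by Tmem181b-ps (-1.64) and Zfp365 (-1.06). Rps2 did not pass without E18.5 fiber replicate 3 (1.91) or with only the groups compared (adjusted p = 0.0624). Col4a4 did not pass without P0.5 fiber replicate 3 (0.94), with DESeq2 (adjusted p = 0.0831) or with only the groups compared (adjusted p = 0.0688), nor Zfp365 without E18.5 fiber replicate 3 or P0.5 fiber replicate 1 or 2 (-0.99 each) or with crystallins left out (-0.81).

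Epithelium and fiber shared part of their change with age. From E14.5 to P0.5, 343 genes rose in both tissues (83.5 by chance if the calls were independent) and 189 fell in both (20.9 by chance), while 33 rose in epithelium and fell in fiber and 9 fell in epithelium and rose in fiber. The change of the fiber to epithelium difference from E14.5 to P0.5 tests for which genes that difference grew, shrank or turned. It was positive for 468 genes, led by Clic5 (7.43, edgeR adjusted p = 9.24e-08), Pcdh17 (4.94) and Crybb2 (4.92), and negative for 984, led by Sorcs1 (-6.60, edgeR adjusted p = 1.94e-09), Col9a2 (-6.35) and Tmprss11e (-6.14). In epithelium Sorcs1 went from 6.1 CPM at E16.5 to 51.3 at E18.5, Col9a2 from 4.5 to 69.2 and Tmprss11e from 1.1 to 20.85. Pigment and retina markers rose in the same step. Whether these changes lie in lens epithelial cells or in other cells of the epithelium libraries was not tested. Pcdh17, a protocadherin gene, stood at 8.56 CPM ± 0.62 in E14.5 fiber and 94.95 ± 19.3 in P0.5 fiber, and at 14.9 ± 3.07 and 5.41 ± 1.15 in epithelium. Of 16 crystallin genes 7 were positive, 3 with library size only (camera adjusted p = 3.03e-05; adjusted p = 0.49 with an estimated correlation), and of 18 glycolysis and hypoxia genes 7 positive and 1 negative, 1 and 2 with library size only and 3 and 1 with crystallins left out (camera adjusted p = 0.00034; adjusted p = 0.352 with an estimated correlation). Of the pigment cell markers 6 of 8 were negative and of the retina markers 5 of 10, 8 with library size only (camera adjusted p = 0.000852 and 0.0439; adjusted p = 0.49 and 0.552 with an estimated correlation). The counts were 138 and 3260 with library size only, where the median of all genes was -0.68, and 263 and 1490 with crystallins left out, where it was -0.30.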

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

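Of the tests in this part, those of scaling, of an even rise of other cell types, of a change shared with fiber, of a switch between red cell types and of a loss of vessel tissue were chosen only after the result was seen, while the tests of shared deviation between libraries, the interaction and the splits of the libraries were not. Each SE of a difference between medians in this part comes from 2000 resamples of the genes compared. It treats genes that deviate together as independent and leaves out variation between libraries, so it can be too small.

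Pigment and retina markers rose together in epithelium between E16.5 and E18.5: 16 of the 18 members tested passed, with a median log2 change of 2.99, and Pmel went from 2.02 to 53.9 CPM and Tyrp1 from 1.30 to 49.3 CPM. Scaling moves all genes of a library alike and cannot part the members from the rest. The median of the 18 members lay 3.01 (SE 0.40) above that of all other genes tested (-0.02). With 16 of the 18 past 2-fold, such a difference was set by the pattern and is no separate test of scaling. The tables argue against a change shared with fiber, where 0 of the 16 rose in the same step by edgeR (1 at an unadjusted p under 0.05 and 1 by DESeq2, median of the members -0.05). They also argue against a lower share of lens cells that raises other cell types alike, since the median lay 2.43 (SE 0.41) above that of 35 endothelium, mural, macrophage and mesenchyme markers (0.56). Cells of the ciliary margin, iris or retina carried over at dissection are a candidate source: over the 6 E18.5 and P0.5 epithelium libraries the 18 members deviated together from their group means (mean pairwise correlation 0.60), more than 100% of 1000 random sets of like level (95th percentile 0.09). In P0.5 epithelium Pmel stood at 54.8, 51.4 and 23.2 CPM in replicates 1, 2 and 3, and Tyrp1 at 53.2, 45.6 and 26.6. How far the correlation rests on replicate 3 was not tested, and 6 libraries leave little to measure. Deviations from the group means leave out a change of the epithelium with stage, unless replicates of 1 stage differ in age. Whether they do is not known, so such a change stays open, untested. The lens itself expresses at least 3 of the members, Oca2 at 32.6 CPM in E14.5 epithelium and Mitf and Rcvrn with higher levels in fiber.

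All 6 red cell genes tested fell in epithelium from E14.5 to P0.5, the most abundant being Hbb-y at 193 CPM ± 49.3 and Hba-x at 33.2 ± 9.45 in E14.5 epithelium. The 2 genes that primitive and definitive red cells both use, Alas2 (-2.19) and Slc4a1 (-4.38), fell as well. Their falls cannot decide on a switch between these cell types alone, since the amounts of these RNAs in each cell type were not measured. The tables argue against a loss of vessel tissue as a whole: the red cell median, -4.73 with Hbb-bh1 set to its bound of at least 33.9-fold (-6.05 as fitted), differed by -4.60 (SE 1.94) from that of endothelium and mural markers (-0.13). This SE rests on few genes, 6 on the red cell side. Fewer red cells carried over at dissection cannot be told apart from other explanations, since over the 6 E14.5 and E16.5 epithelium libraries the mean pairwise correlation of the 6 genes (0.16) exceeded 88.5% of random sets (95th percentile 0.28), and 6 libraries leave little to measure. A difference in blood content between the stages stays open too, and the adult globins cannot answer it, since they have no count in any of the 24 libraries, for a reason that is not stated.

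All 25 endothelium, mural and macrophage markers tested were lower in fiber than in epithelium, the most abundant in epithelium being Rgs5 at 236 CPM ± 12.6 at P0.5 and Cdh5 at 71.7 ± 4.99 at E14.5, against 504 ± 18.2 for the epithelial gene Cdh1 at E14.5. Scaling moves all genes of a library alike and cannot part these markers from the rest. The median of the 25 members differed by -3.78 (SE 0.38) from that of all other genes tested (-0.03). With all 25 past 2-fold, such a difference was set by the pattern and is no separate test of scaling. Cells of the vessel net and macrophages on the lens surface, taken with the epithelium, are a candidate source: over the 12 epithelium libraries the endothelium markers (mean pairwise correlation 0.69) and the macrophage markers (0.56) each deviated together more than 100% of random sets. The mural markers did not reach the same bound (0.11, above 88.2% of random sets), so for the 3 lists as a set this cannot be told apart from expression in the epithelium itself. Notch3 stands in both the mural and the Notch list, and Pdgfra in both the mesenchyme and the epithelium list.

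A test of the difference between stages found a changed fiber to epithelium difference from E14.5 to P0.5 for 1452 genes, among them 29 of the 57 genes named in the main comparisons and 4 others, Pcdh17, Sorcs1, Col9a2 and Tmprss11e, which are named because they passed this test. The log2 change was positive for 17 of these 33: Clic5 7.43, Pcdh17 4.94, Crybb2 4.92, Tbc1d30 4.76, Fabp5 4.75, Zfyve28 3.30, Crygs 3.24, Trpc6 2.69, Scnn1b 2.48, Cryab 2.33, Peg10 2.14, Cd44 1.91, Cryge 1.37, Pla2g7 1.34, Cryga 1.28, Lin28b 1.23 and Crygd 1.11. It was negative for 16: Grb10 -1.01, Ppl -1.22, Igf2 -1.46, Bub1 -1.51, Sned1 -1.61, Fam43a -1.70, Fam198b -1.97, Htra1 -2.56, Lrrn1 -4.02, Col4a3 -4.17, Miat -4.25, Fam129a -5.33, Col9a3 -5.33, Tmprss11e -6.14, Col9a2 -6.35 and Sorcs1 -6.60. How far other cells of the epithelium libraries add to these changes was not tested. Outlying libraries were not tested for, and the weight of each library was seen only by leaving it out in turn.

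Other splits of the same libraries were compared with the real ones by the number of genes past the threshold. For fiber against epithelium averaged over 4 stages, 1 of 100 splits called as many genes, the real one (4703, highest other 0), a share under 0.05. The other splits mix the tissues, so the tissue difference enters their spread within groups and lowers their counts. With 100 splits the share cannot go below 1 of 100, so chance is unlikely but not excluded. For the interaction, 2 of 100 did. The real split called 1460 genes and the highest other 3310, in which all 6 fiber libraries and 0 of 6 epithelium libraries carried the label of the other stage. That split adds the stage changes of the tissues in place of subtracting them, a structure of the samples. The next highest other called 1327 genes, close to the real count, with 4 of 6 fiber and 0 of 6 epithelium libraries carrying the label of the other stage. The interaction splits shuffle stage labels within each tissue, so a stage change in either tissue alone moves the count. They therefore cannot decide whether chance explains the interaction. The comparisons of 3 against 3 libraries make 10 splits, too few for a share under 0.05, and in each 1 split, the real one, called as many genes. Real and highest other counts for fiber against epithelium were 4168 and 0 at E14.5, 4339 and 0 at E16.5, 5173 and 0 at E18.5 and 5219 and 0 at P0.5. In epithelium they were 286 and 0, 907 and 0 and 99 and 1 for the 3 steps in order and 1649 and 0 for P0.5 against E14.5. In fiber they were 366 and 0, 322 and 2, 31 and 2 and 1469 and 0.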

How the results depend on the processing

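Tests here that were chosen only after the data were seen are the block of stage and replicate, the E14.5 and E16.5 stages alone, E16.5 in place of P0.5, and the fits without Rn45s, Lars2 and Mir6236 or without the genes of the 8 lists for other cell types. The pseudocounts of 0.1 and 0.01 and the list median with a pseudocount of 0.1 apply to normalized values and were not run. Of the named genes under each alternative, 4484 values kept their direction and their side of the threshold, 53 kept the direction but did not pass, and 1 reversed: Lars2 in epithelium, P0.5 against E14.5, at 0.31 without E14.5 epithelium replicate 1 (-4.58 to 0.31 over the libraries left out). Without a fold threshold the counts of genes were, for fiber against epithelium, 9537, 9680, 10234 and 10312 by stage and 11227 averaged; for epithelium 2827, 3823, 1647 and, P0.5 against E14.5, 7304; for fiber 2094, 2746, 769 and 6768; and 5214 for the interaction. With a 4-fold threshold they were 1997, 2116, 2613, 2568 and 2342; 57, 384, 12 and 574; 67, 62, 16 and 357; and 437. These follow from the thresholds. With library size only the counts were 7365 at E16.5, 9094 at E18.5, 8965 at P0.5 and 8010 averaged for fiber against epithelium, 2535 for fiber P0.5 against E14.5 and 3398 for the interaction; the cause was not tested, and with crystallins left out the median of all genes, averaged for fiber against epithelium, was still -0.71, against -1.23 with library size only. Fiber P0.5 against E18.5 gave 144 genes with crystallins left out and 31 with only the groups compared, and epithelium P0.5 against E18.5 gave 80 with a filter of 5 CPM, where fewer genes are tested; for the first and second of these the cause was not tested. Epithelium E16.5 against E14.5, in place of P0.5, gave 314. All other total counts, under median of ratios scaling, DESeq2, no filter and the replicate block among others, stayed within 1.5 times the main count; of the separate counts of higher and of lower genes 924 did and 96 did not. E14.5 and E16.5 alone gave 4238 genes for fiber against epithelium, and without the genes of other cell types the count was 4646. Leaving out each library in turn gave 4103 to 4165, 4245 to 4399, 5111 to 5202, 5163 to 5263 and 4680 to 4735 genes for fiber against epithelium by stage and averaged; 254 to 388, 859 to 966, 100 to 141 and 1593 to 1732 for epithelium; 304 to 412, 291 to 365, 50 to 88 and 1398 to 1538 for fiber; and 1332 to 1490 for the interaction. Replicate numbers were not taken to pair the tissues, since not every pair's deviations correlated over 0.1: the 12 correlations ran from -0.07 to 0.22, with 3 over 0.1. Of 12 epithelium libraries 6 matched the fiber library of their own number best, so pairing in part of the libraries stays open. With the replicate number as a block the counts were 4705 averaged, 128 for epithelium P0.5 against E18.5, 1471 for fiber P0.5 against E14.5 and 1438 for the interaction, and Lars2 in epithelium, P0.5 against E14.5, had an adjusted p = 0.0742. Of the gene lists, 2617 results were the same, 28 no longer passed (22 with an estimated correlation), 50 passed only under the alternative (33 with fry) and 29 reversed, none of which passed either way. The reversed adjusted p-values, the cause of which was not tested, were for glycolysis and hypoxia, averaged, 0.948 (5 CPM), 0.889 (crystallins left out), 0.801 (library size only), 0.950 (replicate block), 0.970 (without P0.5 epithelium replicate 1; 0.904 to 0.982 over the libraries left out) and 0.967 (fry). In epithelium the same list gave 0.792 (5 CPM), 0.946 and 0.841 (without E14.5 or P0.5 epithelium replicate 3; range 0.653 to 0.946) and 0.997 (fry), and long noncoding RNAs 0.984 (only the groups compared). Averaged, red cells gave 0.889 (crystallins left out) and 0.363, retina 0.406 and pigment cells 0.839 (library size only). In fiber, retina gave 0.932 (5 CPM), Wnt 0.975 (crystallins left out) and 0.945 (without E14.5 fiber replicate 3; range 0.754 to 0.981), macrophages 0.955 (crystallins left out) and 0.205 (library size only), endothelium and mural cells 0.567 (library size only), and chromatin 0.913 (without P0.5 fiber replicate 2; range 0.751 to 0.945) and 0.885 (fry). Pigment cells in fiber gave 0.823 (crystallins left out), 0.217 (library size only), 0.893 and 0.972 (without E14.5 or P0.5 fiber replicate 1; range 0.893 to 0.981) and 0.812 (fry). Depth limits the genes near 0: a group of 3 libraries without a count allows a level of up to 0.0685 CPM in E14.5 epithelium and 0.1 CPM in P0.5 fiber.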

Other observations

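Nothing in this part was tested as an explanation, and the genes and steps were chosen only after the result was seen. Genes of glycolysis and of the response to low oxygen moved together in epithelium from E18.5 to P0.5 and in fiber from E16.5 to E18.5. In epithelium from E18.5 to P0.5, 14 of the 18 members tested were lower and Aldoc was higher at an adjusted p under 0.05, with a median log2 change of -0.64 (camera adjusted p = 2.80e-18; adjusted p = 0.00396 with an estimated correlation). Past 2-fold fell Ankrd37 (-1.40 ± 0.22 SE, edgeR adjusted p = 0.000338), Egln3 (-1.10 ± 0.15, edgeR adjusted p = 8.20e-05) and Pgk1 (-1.04 ± 0.14, edgeR adjusted p = 6.87e-05), and adjusted over the list alone the same number passed. Egln3, an oxygen-dependent prolyl hydroxylase gene, went from 22.7 CPM ± 1.84 (SD, n = 3) to 10.6 ± 1.25, and Ldha stood at 401 ± 36.8 and 205 ± 46.2. Bnip3 (-1.24) and the lactate transporter gene Slc16a3 (-1.67) fell in the same step.

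In fiber the same list was higher at an earlier step, from E16.5 to E18.5: 14 of 18 members were higher at an adjusted p under 0.05, with a median of 0.78, and 5 passed 2-fold, Aldoc (2.0), Pdk1 (1.61), Ldha (1.39), Aldoa (1.17) and Egln3 (1.15; camera adjusted p = 3.11e-16; adjusted p = 0.00648 with an estimated correlation). Adjusted over the list alone, 5 passed, and 3 passed with library size only or with crystallins left out. Bnip3 rose in that step (1.29). From E18.5 to P0.5 the median in fiber was -0.26 (camera adjusted p = 1.23e-05; adjusted p = 0.351 with an estimated correlation). Proliferation genes were lower in epithelium at E16.5 than at E14.5, by less than 2-fold: 25 of 26 at an adjusted p under 0.05, with a median of -0.64 (camera adjusted p = 8.86e-22; adjusted p = 0.0346 with an estimated correlation).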
